A study of Escherichia coli and Salmonella enterica subsp. enterica with 16 samples.

How the data were processed

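RNA sequencing libraries from 16 bacterial cultures were analysed, 2 biological replicates in each of 8 groups according to the sample labels. The E. coli groups were wild type and a strain without uhpT and uhpU in LB, and the deletion strain with an empty plasmid or a UhpU plasmid after an arabinose pulse in LB or in M9CA medium with G6P. The Salmonella groups were the corresponding deletion strain with the empty or the UhpU plasmid on G6P. Per the labels' protocols, RNA was extracted with hot phenol, ribosomal RNA was depleted with probes, cDNA was primed with random hexamers and libraries were sequenced on a BGISEQ-500. Per the series design, the pulse libraries carry no strand information and the wild-type and deletion libraries do.

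The authors deposited one table per library, with a locus tag, a gene name and a value per gene. The submitters' processing notes name Bowtie2 and RSEM without versions. The genome build, annotation and filters are not given in the sources used here. The deposited values are of FPKM type, which was established from the values themselves: in E. coli, value times gene length sums to the same total in each library, and between 99.9% and 100% of the low values are whole numbers of reads within a tolerance of 0.1 read. The gene lengths for this check came from the RefSeq gene table of assembly ASM584v2, which was used only for lengths, names and neighbours and not for coordinates. Multiplying back gave between 20700000 and 40900000 reads assigned to genes per E. coli library, so that 3 reads correspond to between 0.0527 and 0.104 FPKM for uhpT. For Salmonella no gene lengths were used here, so the unit was not checked this way and was taken to be the same, the depth of those libraries is unknown, and no floor is given. The tables list 4638 genes for E. coli and 4713 for Salmonella, the latter under locus tags of the STM and PSLT series. No pair of libraries was identical.

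The designs were fixed before the data were examined and assumed read counts. Because the deposited values are FPKM-type values and not counts, the test was replaced by the one that unit needs. Values were transformed as log2(FPKM + 1) without further scaling (in the contrast between species, after scaling each library to the same sum over the shared genes), genes with at least 1 FPKM in at least 2 libraries of a fit were kept, and groups were compared with limma 3.58.1 in R 4.3.3, with variance trended on the mean and Benjamini-Hochberg adjustment at 0.05. Fold changes are therefore on the log2(FPKM + 1) scale and understate changes of genes with low values. The Salmonella pair and the wild-type and deletion pair were each fitted alone with 4 libraries, and the E. coli pulses in one fit of 8 libraries that gave the LB pulse, the G6P pulse, their difference, and G6P against LB in the vector strain. The contrast between species used 2266 tested genes out of 2270 shared gene symbols, after leaving out 2 symbols that name different genes in the species. The mean of the LB and G6P pulse effects was added after seeing the data. With 2 libraries per arm an exact permutation test of a single gene cannot reach 0.05, so p-values rest on limma's moderated test, which borrows variance across genes.

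Lists of genes for pathways and regulons were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, in all comparisons where at least 5 members were tested. The same lists were tested with camera at an estimated correlation and with fry. Besides the adjustment over all genes, members were adjusted over each list alone. Genes named in the text follow a rule fixed at the same stage. It takes uhp and arabinose genes, then up to 10 genes in each direction with the largest change among those past the threshold with a mean of at least 5 FPKM and separated arms, or the 5 genes with the smallest p where fewer than 5 pass, up to 4 members of each list that passes, lrhA and flagellar genes, and for tests of a difference up to 5 genes in each direction. Genes named outside it are said to be chosen after their values were seen.

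Alternatives were median-of-ratios scaling, no filter, leaving out ribosomal and transfer RNA genes, a pseudocount of 0.1, the replicate number as a block, smaller fits, a minimum absolute log2 change of 1, and leaving out each library in turn, in which case the lone library of an arm is assumed to vary like the others. Added after seeing the data were limma-voom on the recovered E. coli reads (genes with at least 10 reads), crossed replicate numbers, and the record of which genes and lists were called without each library. Overlaps between comparisons were tested with a one-sided Fisher's exact test.

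The procedure was tested on simulated values made from the means of the real libraries and limma's moderated variances, with 200 changed genes. These variances are already drawn toward the trend, and the changed genes had a mean value of at least 5. The shares recovered can therefore be too high for the real libraries. For the Salmonella comparison, with 4512 genes, 97% of genes changed by 1 on the log2 scale and 100% of those changed by 2 were recovered, with 10 false calls. For the LB pulse the shares were 47% and 100% (4429 genes, 7 false calls), for the deletion 34% and 99% (4325 genes, 7 false calls), for both media together 88% and 100% (16 false calls), for the difference between media 6% and 74% (4 false calls), and for the difference between species 30% and 98% (2266 genes, 8 false calls). Of 20 simulated lists of 30 genes in the Salmonella comparison, the 1 shifted list was called and 0 others were. The simulated genes varied independently of each other, so effects of whole libraries were not simulated. This also does not test camera on lists whose members vary together. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.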

Results

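UhpU is a small RNA that comes from the 3′ end of the uhpT transcript, and uhpT encodes the transporter that takes up hexose phosphates such as glucose 6-phosphate (G6P). The series asked which transcripts respond when UhpU is supplied for a short time or is missing. RNA was sequenced from 16 cultures in 8 groups, with 2 biological replicates in each group. Salmonella Typhimurium SL1344 and Escherichia coli MG1655, both without uhpT and uhpU, carried either an empty arabinose-inducible plasmid (vector) or the same plasmid with UhpU, a fragment of 72 nt in Salmonella and 265 nt in E. coli. Arabinose at 0.2% was present for 10 min at 37 °C in both arms. Salmonella was pulsed in M9CA medium with 0.1% G6P at an optical density of about 0.5, and E. coli in that medium and in LB. The labels disagree on the density of the LB pulses, giving 0.5 for the samples and 1.0 for the series. Wild-type E. coli and the deletion strain were compared in LB at a density of about 1.0 without a plasmid pulse. Between 20700000 and 20900000 reads were assigned to genes in each wild-type and deletion library and between 28600000 and 40900000 in each E. coli pulse library, to 3 digits, while the depth of the Salmonella libraries is unknown. Values are reads per kilobase of gene, scaled to the assigned reads of the library (FPKM), given as mean ± SD with n = 2. This unit was checked with gene lengths in E. coli and taken over for Salmonella without that check. Changes are log2 fold changes of FPKM plus 1 with their standard error (SE), a scale that understates the change of genes with low values.

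The deleted gene was checked first in every library. uhpT stood at 12.8 and 11.6 FPKM in the wild-type E. coli replicates and at 0.414 and 0.277 in the deletion replicates, which corresponds to 367 and 338 reads against 12 and 8. It lay between 0 and 0.25 in the 8 E. coli pulse libraries. In Salmonella, uhpT was at 0.614 and 0.714 with the vector and 0.526 and 1.02 with UhpU. The arabinose isomerase gene araA, induced by the inducer itself, reached 6092 ± 12 FPKM with the vector and 6360 ± 22.6 with UhpU in the LB pulses, against 11.3 ± 6.99 in the wild type. The annotated uhpU gene of E. coli did not differ between UhpU and vector (0.10 in LB and −0.06 in G6P on the log2 scale). No uhpU value was listed for Salmonella. How much UhpU the plasmids made was therefore not verified in either species, and why uhpU did not rise was not tested. In E. coli, uhpU was listed at 0 in both wild-type and both deletion libraries. It lay between 1.59 and 7.63 FPKM in the 8 pulse libraries, although their strain lacks uhpU. Without strand information in the pulse libraries, reads of a gene and of an overlapping or antisense neighbour cannot be told apart.

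**Figure D1:**
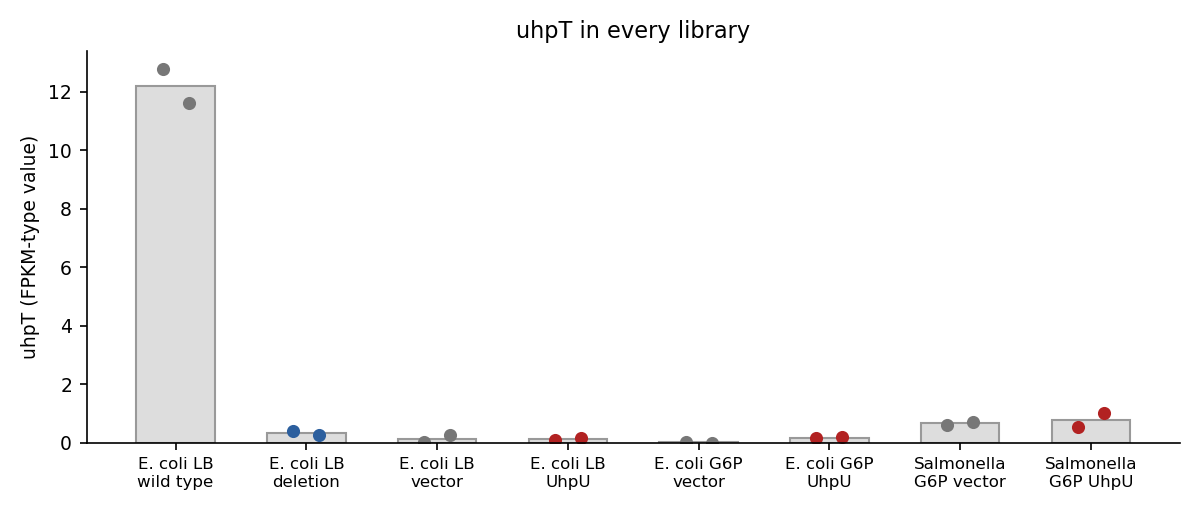
Points show uhpT in each of the 16 libraries as FPKM-type values and bars the mean of the 2 replicates of a group. The wild-type libraries stand at 12.8 and 11.6, and every other library lies at 1.02 or below.

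In Salmonella on G6P, genes of sugar uptake through the phosphotransferase system (PTS) fell after the UhpU pulse. manX, which encodes a subunit of the mannose transporter, fell by 3.13 ± 0.16 on the log2 scale, from 392 ± 20.8 to 43.7 ± 0.564 FPKM (limma, adjusted p = 5.86e-05). The neighbouring subunit genes manY and manZ fell by 1.90 ± 0.23 and 1.88 ± 0.17 (adjusted p = 0.00379 and 0.00134). ptsH and ptsI, for the 2 general phosphate carriers of the system, HPr and enzyme I, fell by 2.48 ± 0.18 and 1.80 ± 0.17 (adjusted p = 0.000265 and 0.00135), with ptsH going from 2718 ± 164 to 487 ± 49.3 FPKM. crr, the next gene of the same operon, gave −0.64 ± 0.21 and did not pass (adjusted p = 0.293). nagE, the N-acetylglucosamine transporter of this system, rose by 1.11 ± 0.17 (adjusted p = 0.0143). With each of the 4 libraries left out in turn, manX, manY, manZ, ptsH and ptsI were called every time and nagE only without vector replicate 2. crr and nagE were chosen after their values were seen. Of 16 PTS genes measured, 5 fell and 1 rose over all genes tested, and 6 fell and 1 rose adjusted over the list alone. The list passed camera (median −0.10, mean −0.63, adjusted p = 0.00112), with adjusted p = 0.755 with an estimated correlation.

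Invasion genes fell in the same cells. hilC and hilA, regulators of the invasion-associated secretion system of Salmonella pathogenicity island 1 (SPI-1), fell by 1.77 ± 0.16 and 1.70 ± 0.17 (limma, adjusted p = 0.00106 and 0.00135), hilA from 121 ± 8.46 to 36.4 ± 3.38 FPKM. prgJ and prgK, which encode parts of the needle complex, fell by 1.10 ± 0.18 and 1.03 ± 0.16 (adjusted p = 0.023 and 0.018), and the chaperone gene invB by 0.90 ± 0.16 (adjusted p = 0.0273). hilD, another regulator of the island, gave −0.62 ± 0.17 (adjusted p = 0.188). Of these, invB and hilD were chosen after their values were seen. Over all genes 5 of the 38 SPI-1 genes found by symbol fell and adjusted over the list alone 16 did, while 36 had a negative fold change. The list median was −0.42 (camera adjusted p = 1.19e-15, and adjusted p = 0.755 with an estimated correlation). hilC and hilA were called without each library in turn, and prgJ, prgK and invB only without vector replicate 2, whose removal raised the count of calls over all genes from 85 to 117. Type 1 fimbria genes had negative fold changes in 9 of 9 members, with a median of −0.49 (camera adjusted p = 1.16e-05, and adjusted p = 0.755 with an estimated correlation). Among them fimC, the fimbrial chaperone gene, fell by 0.84 ± 0.16 (adjusted p = 0.0418), a call lost without each of the 4 libraries, and 4 members fell adjusted over the list alone.

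Genes of electron transfer and of peptide uptake rose. fdoG, fdoH and fdoI, which encode the aerobically made formate dehydrogenase, rose by 1.57 ± 0.18, 1.98 ± 0.19 and 2.15 ± 0.24 (limma, adjusted p = 0.00307, 0.00135 and 0.00239). nuoH and nuoC, for subunits of the proton-pumping NADH dehydrogenase, rose by 1.47 ± 0.21 and 1.11 ± 0.17 (adjusted p = 0.0113 and 0.0169), nuoH from 98 ± 25.3 to 270 ± 40.9 FPKM, and nuoJ of the same enzyme rose by 1.53 ± 0.31 (adjusted p = 0.0481). The list of NADH dehydrogenase, oxidase and ATP synthase genes had 9 of 30 members higher over all genes, 14 adjusted over the list alone and 25 with a positive fold change (median 0.49, camera adjusted p = 3.8e-14, and adjusted p = 0.755 with an estimated correlation). sdhA and sdhB of succinate dehydrogenase rose by 1.08 ± 0.18 and 1.28 ± 0.22 (adjusted p = 0.0261 and 0.029), as did the fumarase gene fumA by 1.03 ± 0.16 and the aconitase gene acnA by 0.98 ± 0.16 (adjusted p = 0.0179 and 0.0184). Together 6 of 20 tricarboxylic acid (TCA) cycle genes rose, 7 adjusted over the list alone (median 0.13, camera adjusted p = 0.000921, and adjusted p = 0.755 with an estimated correlation). The dipeptide permease genes dppB, dppF, dppC and dppD rose by 1.76 ± 0.23, 1.75 ± 0.17, 1.69 ± 0.19 and 1.66 ± 0.17, with adjusted p between 0.00135 and 0.00572, while dppA, for the binding protein in front of them, gave 0.75 ± 0.18 (adjusted p = 0.105). gltK of the glutamate transporter rose by 1.12 ± 0.23 (adjusted p = 0.0483), so that 5 of 28 peptide and amino acid transport genes rose (median 0.42, camera adjusted p = 7.76e-05, and adjusted p = 0.755 with an estimated correlation). Adjusted over that list alone, 14 rose and 5 fell. The genes dppA and gltK were chosen after their values were seen.

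Several of the calls on single electron transfer genes depended on single libraries. fdoH, fdoI, dppC, dppD and dppF were called without each library in turn. fdoG and dppB were lost only without UhpU replicate 2 (adjusted p = 0.0593 and 0.0708). nuoH was lost without vector replicate 1 and without UhpU replicate 2 (largest adjusted p = 0.16). nuoC, nuoJ, sdhA, sdhB, fumA, acnA and gltK were called only when vector replicate 2 was left out. Fold changes of all these genes kept their direction in each of the 4 fits. The PTS, SPI-1, fimbria, NADH dehydrogenase and peptide transport lists kept their camera calls in all 4, while the TCA cycle list lost its call without vector replicate 2 (median 0.23, adjusted p = 0.0971). The NADH dehydrogenase median was 0.28 without vector replicate 1 and 0.31 without UhpU replicate 2, and the PTS median −0.17 without UhpU replicate 2. Across all genes, vector replicate 1 correlated at 0.990 with vector replicate 2 and at 0.986 and 0.982 with the UhpU libraries, while vector replicate 2 reached 0.992 and 0.991 with the UhpU libraries.

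**Figure D2:**
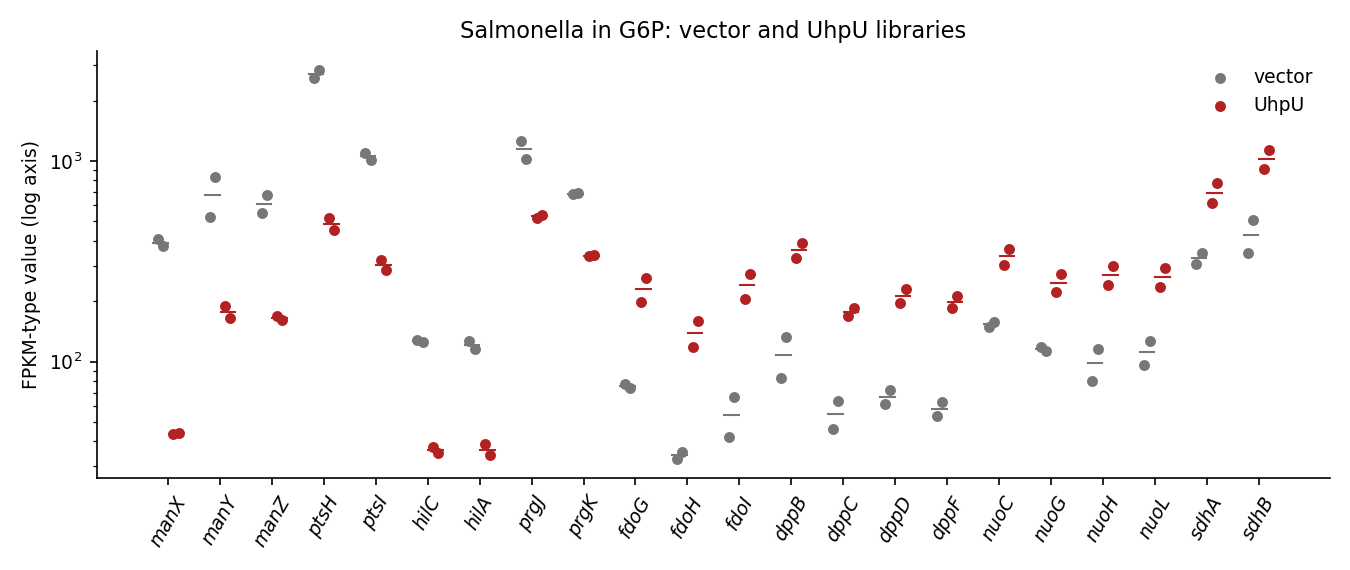
Points are the FPKM-type values of 22 Salmonella genes in the vector and UhpU libraries, short lines the mean of 2 replicates, on a log axis. For manX the UhpU libraries average 43.7 against 392 with the vector, and for fdoH they average 139 against 34.1.

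The remaining genes with the largest changes in Salmonella matched no tested list by name. Lists were matched by gene symbol, so a gene given only by its locus tag was not counted in any list. STM4314, chosen after its values were seen, gave −2.64 ± 0.29 (limma, adjusted p = 0.00239). It dropped below the filter on low values without either vector replicate. STM4313, STM1249, STM4315, yobA and STM4312 fell, with log2 fold changes of −2.55, −2.45, −2.44, −2.42 and −2.09, and each was called without each library in turn. yaaY rose by 1.34, called only without vector replicate 2. In total 38 genes rose and 47 fell of 4512 tested (limma with trended variance, Benjamini-Hochberg), among them 25 and 31 with a change of at least 1. Over all tested genes, the UhpU and vector libraries did not overlap in 35.4%, where chance gives 33.3%. With only 1 library in an arm, the count was 32 without vector replicate 1, 117 without vector replicate 2, 27 without UhpU replicate 1 and 23 without UhpU replicate 2, and 16 of the lower and 5 of the higher genes were called in all 4 of these fits. Median-of-ratios scaling left 50 calls, 18 higher and 32 lower, and all 85 genes kept their direction.

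Flagellar genes, on which UhpU has been reported to act in E. coli, did not pass in Salmonella. The regulators flhD and flhC gave −0.17 and −0.18 on the log2 scale, the sigma factor gene fliA −0.15, and the flagellin genes fliC and fljB −0.10 and −0.05. The 56 flagellar and chemotaxis genes had a median of −0.06 (camera adjusted p = 0.473). lrhA, which encodes a repressor of flagellar genes, stood at 153 and 222 FPKM with the vector and at 111 and 118 with UhpU (−0.68 ± 0.20, adjusted p = 0.215), a gene chosen here after its values were seen. The sugar phosphate stress list passed with 3 of 8 members lower, and these were manX, manY and manZ (median −0.07, camera adjusted p = 0.0104, and adjusted p = 0.929 with an estimated correlation), but not without vector replicate 2 (adjusted p = 0.0998). Its other 5 members gave between −0.19 and 0.48 and were not called, and its median was −0.24 without UhpU replicate 1 and 0.08 without UhpU replicate 2. Of the other lists that passed, branched-chain amino acid synthesis (median 0.14, camera adjusted p = 0.0142) lost its call without vector replicate 2 (median 0.14) and without UhpU replicate 2 (median 0.29). The cysteine and sulfate list (median 0.32, camera adjusted p = 0.00677) lost it without vector replicate 1 (median −0.10, adjusted p = 0.749) and UhpU replicate 1 (median 0.00, adjusted p = 0.71), and its median was 0.83 without vector replicate 2 and 0.77 without UhpU replicate 2. Anaerobic respiration (median 0.08, camera adjusted p = 0.0427), with 4 genes higher and 2 lower, lost it without vector replicate 1 (0.0509), vector replicate 2 (0.0998) and UhpU replicate 2 (0.258) and under median-of-ratios scaling (0.0524). With an estimated correlation the adjusted p of these 3 lists was 0.755 or 0.929.

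In E. coli in LB, no gene passed after the UhpU pulse. The genes with the smallest p, named as not passing, were mprA, a repressor of a multidrug efflux pump (−1.85 ± 0.19, 292 ± 17.5 to 80 ± 0.962 FPKM, limma adjusted p = 0.0575), ptsH (−1.56 ± 0.19, adjusted p = 0.0927), yabR (−1.65 ± 0.23), the dipeptide permease gene dppF (1.59 ± 0.24) and artI, for an arginine-binding protein (−1.56 ± 0.24), the last 3 at an adjusted p of 0.116. lrhA had values of 114 ± 1.11 with the vector and 62.9 ± 1.1 with UhpU (−0.85 ± 0.20, adjusted p = 0.351). flhD gave 0.17, flhC 0.33, fliA 0.15 and fliC 0.10, and none of these passed. limma called 0 of 4429 genes, where 166 had an unadjusted p under 0.05 against 221 that chance gives, and limma-voom on recovered reads also called 0. A pseudocount of 0.1 gave 4 genes, all lower.

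At the level of gene lists in LB, 10 of 36 passed camera. Of the list of ethanolamine and propanediol use, 17 genes were tested in E. coli against 33 in Salmonella. Its E. coli genes named in this report are all ethanolamine (eut) genes. This list had 14 of 17 members with a positive fold change (median 0.49, adjusted p = 1.93e-13), 7 of them higher adjusted over the list alone. Peptide and amino acid transport had 23 of 28 (median 0.15, adjusted p = 1.04e-08), with 3 genes higher adjusted over the list alone. Flagella and chemotaxis had 50 of 54 (median 0.15, adjusted p = 3.37e-05). With an estimated correlation each of these gave an adjusted p = 0.872. Of the 8 libraries of the fit, only those in LB enter these fold changes. The first and the second list kept their calls without each of the 8, with the transport median at 0.29 without LB vector replicate 1. Vector replicate 1 decided several others, since only 4 of the 10 lists kept their call and direction without it. Without that library the flagellar list had a median of 0.00 (adjusted p = 0.684) and the ribosomal protein list went from a median of 0.17 (adjusted p = 0.0199, and adjusted p = 0.933 with an estimated correlation) to −0.43 (adjusted p = 6.85e-09). Without vector replicate 2 the flagellar and ribosomal medians were 0.27 and 0.78, and 8 lists kept call and direction, and 7 did without UhpU replicate 1 and again without UhpU replicate 2. The ribosomal median was −0.04 without UhpU replicate 2. Under median-of-ratios scaling it was 0.21 and the list did not pass (camera adjusted p = 0.101).

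In E. coli on G6P, again no gene passed. The smallest p values belonged to mprA (−1.45 ± 0.19, 185 ± 27.7 to 66.6 ± 4.5 FPKM), the ethanolamine genes eutP (1.83 ± 0.25, 1.58 ± 0.147 to 8.19 ± 0.269 FPKM), eutQ (1.84 ± 0.25) and eutM (1.51 ± 0.22), and xylR, the activator of xylose genes (−1.59 ± 0.23), each at a limma adjusted p of 0.112. mglB, for the galactose-binding protein, gave −2.76 ± 0.48 (adjusted p = 0.168) and atpG of ATP synthase −1.01 ± 0.24 (adjusted p = 0.317). lrhA gave −0.35 ± 0.20 (adjusted p = 0.906), and flhD, flhC, fliA and fliC gave 0.23, 0.16, 0.15 and 0.27. limma called 0 of 4429 genes, where 288 had an unadjusted p under 0.05, and limma-voom also called 0. Without vector replicate 1 the count was 11, 4 higher and 7 lower.

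Lists on G6P separated more widely, and 13 of 36 passed camera. Ethanolamine and propanediol use had 17 of 17 members with a positive fold change (median 0.60, adjusted p = 7.07e-18), and 10 were higher adjusted over the list alone. NADH dehydrogenase, oxidase and ATP synthase genes had 27 of 33 negative (median −0.59, adjusted p = 5.76e-12), and TCA cycle genes 19 of 21 (median −0.38, adjusted p = 0.000321). Branched-chain amino acid synthesis had 19 of 19 positive (median 0.41, adjusted p = 6.67e-07), type 1 fimbriae 10 of 10 positive (median 0.39, adjusted p = 0.00018), and pyrimidine synthesis 13 of 13 negative (median −1.46, adjusted p = 9.35e-10), 6 of these lower adjusted over the list alone. These 6 lists kept their calls without each of the 8 libraries, and gave an adjusted p of 0.648 or 0.75 with an estimated correlation. Only the G6P libraries enter their fold changes, so leaving out an LB library did not move their medians. Their size varied with the libraries. The pyrimidine median was −0.46 without G6P vector replicate 2 and −2.79 without G6P vector replicate 1, and that of branched-chain amino acids 0.11 and 0.72. The TCA cycle median was −0.13 without G6P UhpU replicate 1, the NADH dehydrogenase median ranged from −0.70 to −0.43, the ethanolamine median was 0.40 without G6P vector replicate 2, and the fimbria median 0.22 without G6P UhpU replicate 2. Vector replicate 2 stood apart for nucleotide synthesis, and only 6 of the 13 lists kept their calls without it. The aspartate carbamoyltransferase gene pyrB, chosen after its values were seen, was at 193 and 1059 FPKM in vector replicates 1 and 2 and at 5.04 and 109 with UhpU. Both arms thus varied widely for this gene. Purine synthesis (median −1.12, adjusted p = 9.35e-10) and ribosomal protein genes (median −0.56, adjusted p = 1.91e-12) gave medians of −0.25 and −0.10 without vector replicate 2 (adjusted p = 0.0591 and 0.334) and of −2.19 and −1.09 without vector replicate 1. With an estimated correlation their adjusted p was 0.75 and 0.857. Without UhpU replicate 1, 10 of the 13 lists kept their calls, and 12 or 13 did without each of the remaining libraries.

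A combined test over both media, added after the single pulses had been examined, took the mean of the LB and G6P effects. mprA fell by 1.65 ± 0.14 and ptsH by 1.42 ± 0.13 on the log2 scale (limma, adjusted p = 0.0103 and 0.0146). xylR fell by 1.37 ± 0.16, artI by 1.42 ± 0.17, the small RNA gene glmZ by 1.34 ± 0.15 (adjusted p = 0.0202 each) and nagE by 1.21 ± 0.16 (adjusted p = 0.0278). Lower too were mglB and rbsD of the alternative sugar use list, by 1.97 ± 0.34 and 1.66 ± 0.26, and tsx, for a nucleoside channel, by 1.24 ± 0.20 (adjusted p = 0.0494, 0.0426 and 0.0426). The ethanolamine genes eutP, eutM and eutQ rose by 1.48 ± 0.18, 1.45 ± 0.15 and 1.39, and 7 of 17 members of their list rose over all genes and 11 adjusted over the list alone (median 0.57, camera adjusted p = 2.68e-20, and adjusted p = 0.874 with an estimated correlation). ompX, for an outer membrane protein, and hfq, for the RNA chaperone, rose by 1.35 ± 0.19 and 1.22 ± 0.17 (adjusted p = 0.0303 each), and the small RNA gene micA by 1.12 ± 0.18 (adjusted p = 0.0431). tsx and micA were chosen after their values were seen. NADH dehydrogenase, oxidase and ATP synthase genes had a median of −0.43 with none past the threshold over all genes and 8 lower adjusted over the list alone (camera adjusted p = 2.67e-10, and adjusted p = 0.874 with an estimated correlation). lrhA gave −0.60 ± 0.14 (adjusted p = 0.206).

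Over both media 13 genes rose and 24 fell of 4429 tested. Chance could not be excluded as the source of these calls when the 8 libraries were divided in other ways. Over all tested genes, the UhpU and vector libraries did not overlap in 23.7% in LB and 36.1% on G6P, where chance gives 33.3%. The split was 12 higher and 14 lower with median-of-ratios scaling and 10 higher and 13 lower with limma-voom. Leaving out a library left 20 calls without LB vector replicate 1, 16 without LB vector replicate 2 and 11 without G6P vector replicate 1, and 0 without each of the other 5 libraries, while 37 of the 37 genes kept their direction in all 8 fits. mprA, ptsH, xylR, glmZ and eutM were called in 3 of these 8 fits, artI, nagE, eutP and eutQ in 2, ompX and hfq in 1, and mglB, rbsD, tsx and micA in 0. Of the 13 lists past camera, 5 were called in all 8: the ethanolamine and NADH dehydrogenase lists, branched-chain amino acid synthesis (median 0.29, camera adjusted p = 1.77e-05), sigma E envelope stress (median 0.18, 0.000605) and type 1 fimbriae (median 0.23, 0.000823), the last 3 with adjusted p = 0.885 with an estimated correlation. Without G6P vector replicate 2 the medians of the ethanolamine, branched-chain and fimbria lists were 0.38, 0.11 and 0.11, the sigma E median was 0.12 without LB UhpU replicate 2, and that of fimbriae 0.14 without G6P UhpU replicate 2. In number, 10 kept call and direction without LB vector replicate 1, 9 without LB vector replicate 2, 7 without G6P vector replicate 2, and 11 to 13 without each of the others. The PTS list (2 genes lower, median −0.10, camera adjusted p = 0.00443, and adjusted p = 0.911 with an estimated correlation) lost its call without LB vector replicate 1 (median −0.03, adjusted p = 0.233) and without G6P UhpU replicate 2 (adjusted p = 0.0577). Its median was −0.21 without LB vector replicate 2, −0.16 without G6P UhpU replicate 1 and −0.15 without G6P vector replicate 1.

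**Figure D3:**
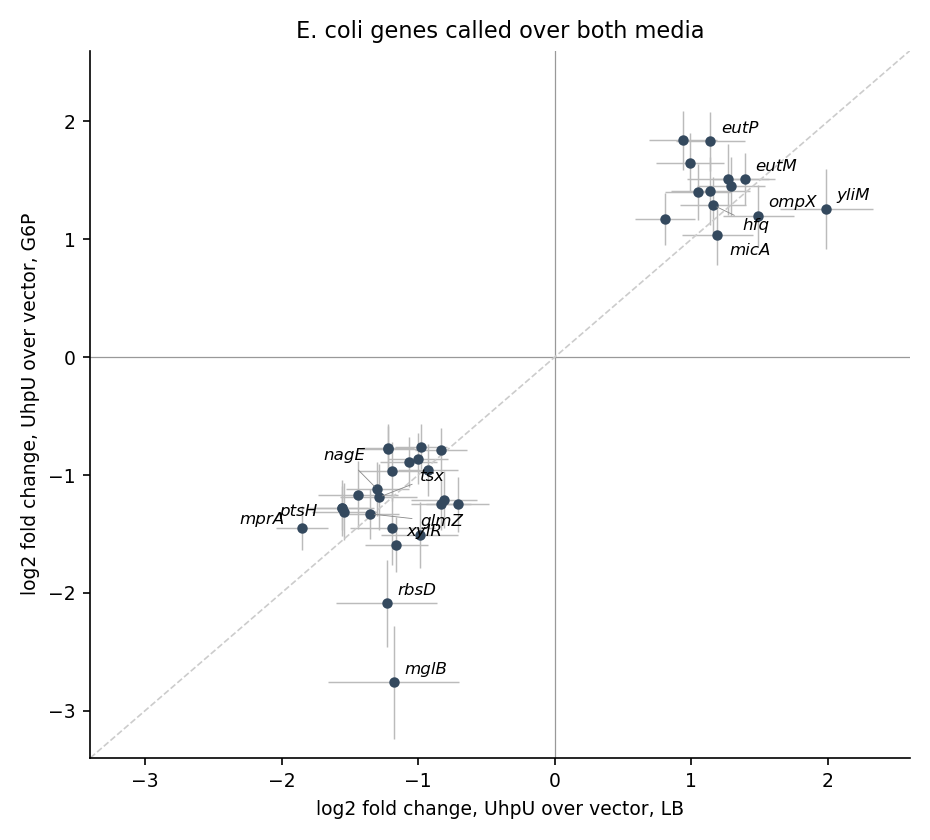
Each point is 1 of the 37 genes called over both media, with its log2 fold change in LB on the horizontal axis and in G6P on the vertical axis, and lines give the SE of each. The dashed line marks equal change, and mprA lies at −1.85 in LB and −1.45 in G6P.

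The difference between the media was tested directly, and no gene passed. The smallest p belonged to yabR (2.22 ± 0.32 more in G6P than in LB, limma adjusted p = 0.582), which was listed at 0 in both LB libraries with UhpU. dppF gave −1.62 ± 0.34 (adjusted p = 0.993) and dppD −1.32. limma called 0 of 4429 genes, 59 had an unadjusted p under 0.05, limma-voom called 0, and a pseudocount of 0.1 gave 1 gene. Among 17 lists past camera were ribosomal proteins (median −0.77, adjusted p = 2.4e-17), NADH dehydrogenase, oxidase and ATP synthase genes (median −0.31, adjusted p = 9.27e-06) and flagella (median −0.36, adjusted p = 1.35e-05), each with adjusted p = 0.721 with an estimated correlation. The NADH dehydrogenase list lost its call without G6P vector replicate 2 (median −0.11, adjusted p = 0.0578). The ribosomal list kept its call, with a median of −0.15 without LB vector replicate 1 and −1.35 without LB vector replicate 2, and so did the flagellar list, with −0.03 without LB vector replicate 1 and −0.65 without G6P UhpU replicate 2. Without G6P vector replicate 2 only 10 of the 17 kept their call and direction, and without LB vector replicate 2 only 11.

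**Figure D4:**
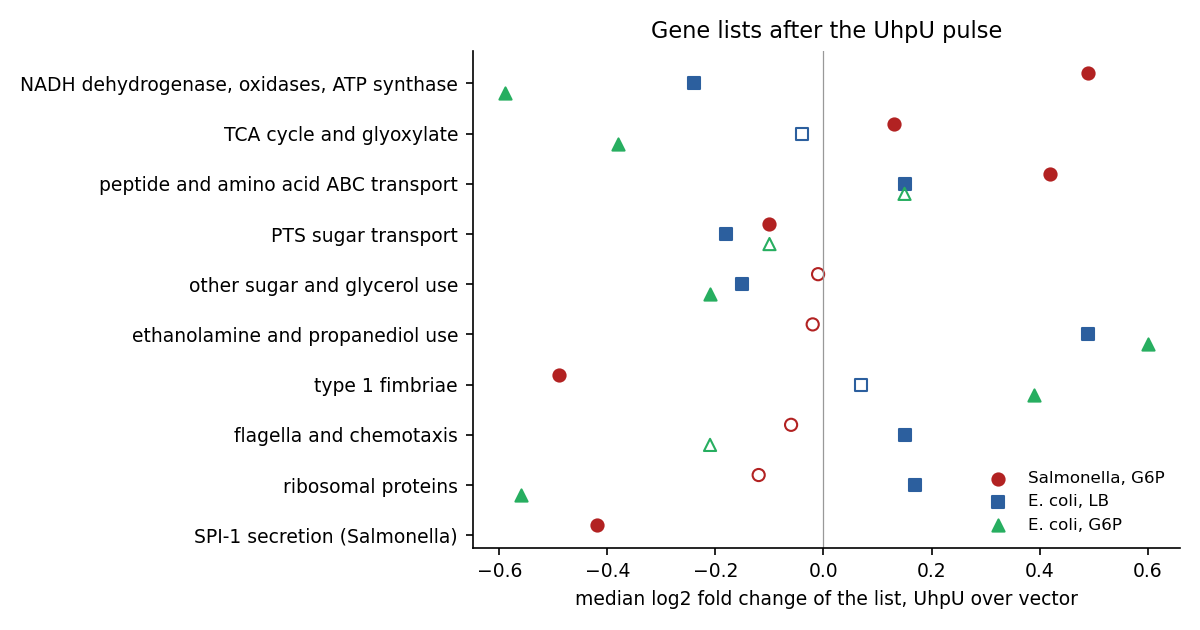
Symbols mark the median log2 fold change, UhpU over vector, of 10 gene lists in Salmonella on G6P and in E. coli in LB and on G6P, filled where the list passed camera. The NADH dehydrogenase list lies at 0.49 in Salmonella and at −0.59 in E. coli on G6P.

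Far more genes of the E. coli vector strain differed between M9CA medium with G6P and LB than between UhpU and vector. Base medium, G6P and, by the series label, density (0.5 against 1.0) changed together, and the strain lacks uhpT. These changes cannot be assigned to G6P itself. trpE and leuA, the first genes of tryptophan and leucine synthesis, rose by 6.25 ± 0.41 and 6.19 ± 0.41 on the log2 scale, trpE from 1.91 ± 0.565 to 219 ± 21.4 FPKM (limma, adjusted p = 4.68e-05). Of 19 histidine and tryptophan synthesis genes 17 rose (median 1.41), as did 14 of 19 for branched-chain amino acids (median 1.34), 9 of 12 for arginine (median 1.52) and 10 of 15 for methionine (median 1.11). The thiamine synthesis gene thiE and the periplasmic acid chaperone gene hdeB rose by 5.56 ± 0.24 and 5.46 ± 0.25, and 23 of 30 genes of the general stress response (RpoS) rose (median 2.41). The outer membrane porin gene ompF rose by 3.63 ± 0.27. tnaA, for tryptophanase, fell by 9.08 ± 0.39, from 27278 ± 6451 to 50.7 ± 19.6 FPKM (adjusted p = 9.48e-06). The heat shock genes ibpB and htpG fell by 7.72 ± 0.49 and 6.17 ± 0.27, with 18 of 19 members of their list lower (median −3.52), and 42 of 75 genes of alternative sugar use fell (median −1.22).

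Further groups also changed between the media. Purine synthesis had 11 of 19 genes higher (median 2.08), peptide and amino acid transport 13 of 28 (median 0.77), curli and cellulose 9 of 15 (median 1.13) and acid resistance 12 of 24 with 2 lower (median 1.09). Flagella and chemotaxis had 10 of 54 lower and 1 higher (median −0.58), TCA cycle genes 10 of 21 lower and 4 higher (median −0.86), NADH dehydrogenase, oxidase and ATP synthase genes 15 of 33 lower and 4 higher (median −0.71), and anaerobic respiration 22 of 60 lower and 4 higher (median −0.24). lrhA rose by 0.71 ± 0.20, from 114 to 187 FPKM (limma, adjusted p = 0.0328), and flhD gave −1.13 (adjusted p = 0.056). These lists, those of amino acid synthesis, general stress, heat shock and alternative sugars, and iron uptake (median 0.75, adjusted p = 0.0167) made up 16 of 36 lists past camera, with adjusted p between 7.2e-16 and 0.0167, and between 0.592 and 0.893 with an estimated correlation. Iron uptake lost its call without LB vector replicate 2 (0.124) and G6P vector replicate 2 (0.384), and the TCA cycle list without LB vector replicate 1 (0.069). The purine and anaerobic medians were 1.16 and −0.14 without G6P vector replicate 2, those of branched-chain amino acids and curli 0.84 and 0.75 without G6P vector replicate 1, and those of flagella and iron uptake −0.38 and 0.48 without LB vector replicate 2.

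In all, 747 genes rose and 653 fell of 4429, 484 and 469 of them by at least 1. The median over all genes was 0.10, and median-of-ratios scaling, which removes that shift, gave 705 higher and 778 lower. limma-voom gave 706 and 781. The count went to 688 without G6P vector replicate 1.

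Deleting uhpT and uhpU in LB left one gene far from the rest. uhpT itself gave −3.29 ± 0.16 (12.2 ± 0.823 to 0.346 ± 0.0974 FPKM), at a limma adjusted p of 0.0639, the smallest of the comparison. The next were ytiD (1.38), ymiB (1.25), yriA (1.12 ± 0.14) and ytjE (1.04), all at an adjusted p of 0.999. uhpC, uhpB and uhpA, which lie beside uhpT and encode its regulators, gave 0.07, 0.26 and 0.36. lrhA gave −0.07 ± 0.29, flhD 0.28, flhC 0.25, fliA −0.05 and fliC −0.12, each at an adjusted p of 0.999. limma called 0 of 4325 genes, where 31 had an unadjusted p under 0.05 against 216 that chance gives, and limma-voom on recovered reads called 0.

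Wild-type replicate 2 stood apart in this comparison. Its correlation across genes with the other wild-type library was 0.967 and with the deletion libraries 0.976 and 0.968, while wild-type replicate 1 reached 0.993 and 0.997 with the deletion libraries. Without wild-type replicate 1 the count of genes went from 0 to 162, with 88 higher and 74 lower. 13 of 36 lists passed camera, among them ribosomal proteins with 54 of 54 positive (median 0.25, adjusted p = 1.65e-06), purine synthesis with 19 of 19 positive (median 0.50, adjusted p = 7.48e-07), general stress genes with 28 of 30 negative (median −0.28, adjusted p = 1.03e-07) and alternative sugar use with 68 of 75 negative (median −0.33, adjusted p = 3.52e-08). Each of these gave adjusted p = 0.784 with an estimated correlation. Without wild-type replicate 2 only 1 of the 13 lists kept its call and direction, and 11 changed direction. Among these, medians were then −0.10 for ribosomal proteins, −0.04 for purine synthesis and 0.18 for alternative sugars. The general stress median stayed negative, at −0.02. Without wild-type replicate 1 the medians were 0.61 for ribosomal proteins, 1.13 for purine synthesis, −0.50 for general stress and −0.81 for alternative sugars. The other 3 libraries, left out in turn, kept 12 lists (wild-type replicate 1), 8 (deletion replicate 1) and 10 (deletion replicate 2).

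Whether Salmonella and E. coli responded differently on G6P was tested over 2266 genes that share a symbol. The mannose transporter gene manX differed by −3.76 ± 0.35 on the log2 scale, with −3.13 in Salmonella and 0.63 in E. coli (limma, adjusted p = 0.00159). manZ differed by −2.31 ± 0.36 (adjusted p = 0.0235). nagE differed the other way, by 2.23 ± 0.32 (1.11 and −1.12, adjusted p = 0.02). The electron transfer genes fdoH and nuoC were higher in Salmonella by 1.84 ± 0.32 (1.98 and 0.15) and 1.73 ± 0.30 (1.11 and −0.62), and dppF by 1.78 ± 0.32 (1.75 and −0.03), each at an adjusted p of 0.0356. The ethanolamine genes eutQ and eutT were lower in Salmonella by a difference of −2.20 ± 0.32 and −1.86 ± 0.25 (adjusted p = 0.02 each), with −0.31 and −0.18 in Salmonella against 1.84 and 1.65 in E. coli. In E. coli eutQ went from 1.52 ± 0.472 to 7.97 ± 1.05 FPKM. The Salmonella values of the eut genes are low, near the minimum of the test, where the scale used understates a response.

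Among lists, the respiratory one had the smallest camera p for a difference between the species. NADH dehydrogenase, oxidase and ATP synthase genes had a positive difference in 29 of 30 members, 6 past the threshold over all genes and 16 adjusted over the list alone (median 1.07, camera adjusted p = 3.64e-20, and adjusted p = 0.584 with an estimated correlation). TCA cycle genes had a median difference of 0.79, with 6 of 18 higher adjusted over the list alone (camera adjusted p = 2.57e-05, and adjusted p = 0.584 with an estimated correlation). Ethanolamine and propanediol use had 17 of 17 negative, 4 past the threshold and 7 adjusted over the list alone (median −0.66, camera adjusted p = 5.12e-13, and adjusted p = 0.584 with an estimated correlation). Of these 4 genes, eutD and eutP, the latter chosen after its values were seen, did not pass the filter on low values in Salmonella alone, so their difference rests on the E. coli values. These 3 lists were among those that kept their calls without each of the 8 libraries, with the TCA cycle median at 0.45 without E. coli UhpU replicate 1 and the ethanolamine median at −0.43 without E. coli vector replicate 2. In all, 16 of 35 lists passed, and 11 kept their calls without E. coli vector replicate 2 and 12 without E. coli UhpU replicate 1. The PTS list (1 gene higher and 4 lower, median −0.08, camera adjusted p = 0.0251, and adjusted p = 0.796 with an estimated correlation) lost its call without Salmonella vector replicate 2 (0.0561), E. coli vector replicate 1 (0.123) and E. coli UhpU replicate 1 (0.094) and under median-of-ratios scaling (0.0528). Its median turned to 0.07 without E. coli vector replicate 2 and to 0.05 without Salmonella UhpU replicate 2, and was −0.24 without E. coli vector replicate 1, −0.19 without Salmonella UhpU replicate 1, −0.15 without Salmonella vector replicate 1 and −0.01 without Salmonella vector replicate 2.

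For single genes, the difference was larger in Salmonella for 13 and smaller for 14 of 2266, or 7 and 13 with median-of-ratios scaling. The count depended on each library. It was 0 without Salmonella vector replicate 1, 2 without Salmonella vector replicate 2, 1 without Salmonella UhpU replicate 1 and 2 without Salmonella UhpU replicate 2. Leaving out E. coli libraries gave 141 without vector replicate 1 (87 higher and 54 lower), 1 without vector replicate 2, 9 without UhpU replicate 1 and 47 without UhpU replicate 2. manX was called in 7 of these 8 fits and lost without Salmonella vector replicate 1 (adjusted p = 0.0582). eutQ and eutP were called in 4, manZ, nagE, eutT and eutD in 3, and fdoH, nuoC and dppF in 2 of them. All 27 genes kept their direction in the 8 fits.

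**Figure D5:**
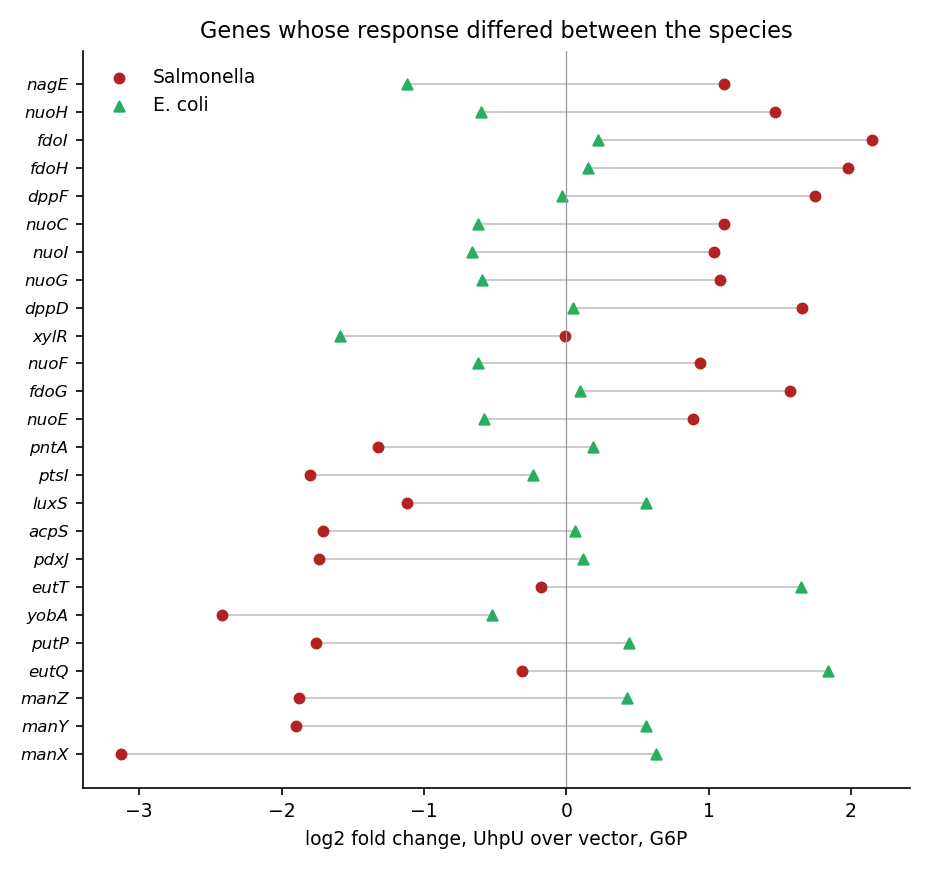
For genes whose response on G6P differed between the species and that were tested in both, circles give the log2 fold change, UhpU over vector, in Salmonella and triangles that in E. coli. manX lies at −3.13 in Salmonella and 0.63 in E. coli.

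Changes shared between comparisons were counted last. No gene was past the threshold in both E. coli pulses, nor in the G6P pulse and Salmonella, because limma called none in either E. coli pulse. At an unadjusted p under 0.05, 21 genes were higher in both media of E. coli against 1.09 that independent lists give, and 46 were lower in both against 4.97, among them mprA, ptsH, nagE, mglB and xylR, while 1 moved in opposite directions. Both effects come from one fit and share the variance of each gene, so independent lists understate the overlap that chance gives, and no p is given. Across all genes the fold changes in the 2 media had a Spearman rho of 0.12, with genes not independent replicates. Between the E. coli G6P pulse and Salmonella, 17 genes moved the same way at that threshold and 23 the opposite way. Of the former, 10 were higher in both against 3.25 by chance (Fisher's exact test, p = 0.00113) and 7 lower in both against 5.77 (p = 0.355). Of the latter, 19, including nuoC and nuoH, were lower in E. coli and higher in Salmonella against 6.18 by chance (Fisher's exact test, p = 5.98e-06). The test takes genes as independent, while genes of one enzyme, such as the nuo genes, were counted singly. Its p-values here therefore overstate the evidence. Of the genes called over both E. coli media, ptsH and tsx were also lower in Salmonella, against 0.159 by chance (Fisher's exact test, p = 0.0104), and nagE was higher there.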

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

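The tests of scaling and of a wrong label on a wild-type library were chosen only after the result was seen.

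A difference between groups set apart the responses to UhpU on G6P, since limma's test of the difference between Salmonella and E. coli called 13 genes with a higher and 14 with a lower effect in Salmonella. Among the named ones, nagE differed by 2.23, fdoH by 1.84, nuoC by 1.73, nuoF by 1.57 and dppF by 1.78 on the log2 scale, all higher in Salmonella. manX differed by −3.76, manZ by −2.31, eutT by −1.86, eutQ by −2.20 and eutD by −1.67. manX was called in 7 of the 8 fits that leave out 1 library and the others in 2 to 4. The Salmonella values of the eut genes are low, near the minimum of the test.

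Respiratory genes, the list with the smallest camera p between the species, had a median difference of 1.07 over 30 genes, with adjusted p = 0.584 with an estimated correlation. A single E. coli library as its source is excluded, because the smallest median difference without any one E. coli library was 0.87, and the median in E. coli alone stayed between −0.70 and −0.43. What stays open is that UhpU may act on these genes in opposite directions in the 2 species, for which no biological test was run, or that the species differ in their growth at the pulse. The 2 species also carried UhpU fragments of different length, 72 and 265 nt, which the design confounds with species.

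In Salmonella, transfer-messenger RNA alone stands at 439002 to 571096 FPKM, so a shift in such abundant transcripts could move all other values together. This is argued against as the cause of either direction, since the median log2 fold change over all 4512 tested genes was −0.01, with quartiles of −0.15 and 0.14. Rescaling each library by the median of ratios left the median of the 47 lower genes at −1.25 (−1.26 before, median SE 0.17 before and 0.16 after) and that of the 38 higher genes at 1.10 (1.09 before, median SE 0.18 both times). Calls fell in number, to 32 lower and 18 higher, as the degrees of freedom that limma borrows across genes went from 6.78 to 5.09, and with that number held at its first value 53 lower and 42 higher genes were called. Effects of single libraries remain open. Vector replicate 1 correlated at 0.982 to 0.990 with the other 3 libraries and vector replicate 2 at 0.991 and 0.992 with the UhpU libraries. Vector replicate 2 was the only library whose removal raised the count of calls, and removing any other lowered it. With single libraries left out in turn, manX stayed between −3.19 and −3.08 and nuoC between 0.97 and 1.25.

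In the comparison of deletion and wild type, 13 gene lists passed camera although limma called no gene, and with an estimated correlation 0 passed, with adjusted p of 0.784 or 0.875. Without wild-type replicate 2, the library that stands apart from the other 3 libraries, 1 of the 13 lists kept its call and direction and 11 changed direction, which is consistent with that library as the source of most of these calls. A deletion library under a wrong label is excluded, since uhpT stood at 11.6 FPKM in wild-type replicate 2 and at 0.414 and 0.277 in the deletion libraries. Whether the culture or its preparation set this library apart was not tested, and the labels give no batch.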

How the results depend on the processing

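The combined E. coli test, limma-voom and crossed replicate numbers were chosen only after seeing the data, the other settings before. The planned count-based tool and its normalization were not run because the tables hold no counts. Counts of genes within 1.5 times of the main value under a setting are not listed.

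Salmonella gave 85 genes, 50 with median-of-ratios scaling, 56 with a minimum log2 change of 1, and 23 to 117 without 1 library, and at least 83 of the 85 kept their direction in each, the others having fallen below the filter. The E. coli LB pulse gave 0, 4 with a pseudocount of 0.1, and 0 without each of the 4 LB libraries. The G6P pulse gave 0, and 0 to 11 without 1 of the 4 G6P libraries. The deletion gave 0, and 0 to 162 without 1 library. Over both media 37 genes were called, 23 with limma-voom (21 of them among the 37), and 0 to 20 without 1 library. The difference between media gave 0, and 1 with a pseudocount of 0.1. The vector strain on G6P against LB gave 1400, and 688 to 1487 without 1 vector library. The difference between species gave 27, and 0 to 141 without 1 library. For Salmonella under median-of-ratios scaling, holding the borrowed degrees of freedom at the value of the unscaled fit gave 95 calls. The cause was not tested for the others, except that a lone library in an arm leaves fewer degrees of freedom.

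The replicate number as a replicate block gave 216 genes in Salmonella and 101 (76 higher and 25 lower) between species and moved no other count by more than 1.5 times. The numbers share no stated batch, and correlations of same-numbered deviations did not settle whether they pair the samples. These were 0.17 in Salmonella, 0.44 in the LB pulse, −0.12 in the G6P pulse, −0.40 in the deletion and 0.45 for the vector in LB with the vector on G6P. Crossed numbers as a block gave 1 gene in the deletion and 0 in the G6P pulse.

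For gene lists, camera with a preset correlation called 10, 10, 13, 13, 13, 17, 16 and 16 lists in Salmonella, the LB pulse, the G6P pulse, the deletion, both media, the difference between media, the medium and the difference between species. With an estimated correlation it called 0 in each of the 8. fry called 14 in the medium and 0 in the other 7.

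Shared changes at an unadjusted p under 0.05 numbered 67 for the 2 E. coli pulses, 17 for the G6P pulse and Salmonella, and 22 for both media and Salmonella, against 0, 0 and 2 at the adjusted threshold. In E. coli, 3 reads are at most 0.104 FPKM for uhpT and more for shorter genes. For Salmonella, the limit set by depth is unknown.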

Other observations

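The genes named in this section were chosen after their values were seen.

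Several further metabolic and regulatory genes were called in Salmonella after the UhpU pulse. putP, for the proline transporter, fell by 1.76 ± 0.25 (limma, adjusted p = 0.011), a call lost only without UhpU replicate 1 (adjusted p = 0.0968). pdxJ and acpS, neighbours for pyridoxal phosphate and acyl carrier protein synthesis, fell by 1.74 ± 0.20 and 1.71 ± 0.17 (adjusted p = 0.00291 and 0.00143), in each of the 4 fits that leave out 1 library. hupB, for a subunit of the nucleoid protein HU, fell by 1.61 ± 0.21 (adjusted p = 0.00572), and luxS, which makes the autoinducer-2 precursor, by 1.12 ± 0.18, from 618 ± 53.2 to 284 ± 39 FPKM (adjusted p = 0.0184). hupB was lost without vector replicate 1 and UhpU replicate 2, and luxS, frdC and frdD were called only without vector replicate 2. The siderophore receptor gene iroN fell by 1.04 ± 0.21 (adjusted p = 0.0481), while the fumarate reductase genes frdB, frdC and frdD rose by 0.91, 1.30 ± 0.24 and 0.99, and the glutamate synthase genes gltB and gltD by 0.77 ± 0.16 and 0.81 ± 0.16 (adjusted p = 0.0481 and 0.0445). Of these, iroN, frdB, gltB and gltD lost their calls without each of the 4 libraries.

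In E. coli the transfer-messenger RNA, which frees stalled ribosomes, took between 9.9% and 13.3% of assigned reads in the 8 LB libraries and between 21.1% and 25.2% in the 4 G6P libraries. Each G6P library thus lay above each LB library, and the share enters the denominator of every FPKM value. Other genes called over both E. coli media include talB, for transaldolase (−0.94 ± 0.15, adjusted p = 0.0431), maeA, for malic enzyme (−1.08 ± 0.18, adjusted p = 0.0431), and rcsA, for a capsule gene activator (−0.98 ± 0.16, adjusted p = 0.044), which were called in 0, 0 and 1 of the 8 fits that leave out 1 library.

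For the effect over both E. coli media, the 8 libraries were divided in other ways, with medium as a term. The real division gave 39 genes in this simpler model, and 2 of the 34 splits, the real one included, gave as many, so chance cannot be excluded. The highest other split gave 248 genes. It set LB vector replicate 1 apart from the other 3 LB libraries and G6P vector replicate 2 apart from the other 3 G6P libraries, so these samples have a structure that does not follow the plasmids. The correlation of LB vector replicate 1 with the other LB vector library was 0.977.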
